A study of Homo sapiens with 8 samples.

How the data were processed

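RNA carrying 5-methylcytosine (m5C) was profiled by methylated RNA immunoprecipitation sequencing (MeRIP-seq), in which fragmented RNA is pulled down with an antibody against the modified base and sequenced beside the unselected input. The cells were HCT15, an established human colorectal cancer line, either as a control or with a short hairpin RNA against NSUN2, an RNA m5C methyltransferase. There were 8 libraries, an immunoprecipitate (IP) and an input for each of 2 control and 2 knockdown replicates. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was depleted, RNA was cut to short fragments before the pull-down, and libraries were sequenced as paired reads on an Illumina HiSeq instrument.

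The 4 deposited files are peak lists, 1 for each pair of IP and input, so replicates were called separately and not pooled. Per the file headers, each row gives a position, a transcript, a gene symbol, and the peak's own statistics, and the peak names begin with MACS, the name of a peak caller whose version is not given in the sources used here. The deposited score is minus 10 times the log10 of the caller's p, and its lowest value was 50 in all 4 lists. The fold enrichment is a ratio that the authors' caller gave for each peak, from IP and background. The deposited false discovery rate is in percent. Another deposited value, of no fixed unit, is the running number in each peak's name, which was used only as a description. Per the submitters' processing notes, cutadapt 1.9.3, STAR, HISAT2 2.0.4, hg19 and GRCh38 were used, with no role given for each. Peak positions overlapped the GRCh38 span of their own gene in 13.9% to 14.0% of matched peaks per list, so the positions are not GRCh38 ones; they are printed as the files give them, with the start raised by 1 to count from 1, and the other build in the notes is hg19. No file gave read counts, a library size, a strand, a sequence or a part of the transcript, so depth is unknown, and counting error, expression, motifs and untranslated regions were not analysed here. The knockdown itself could not be checked, since no expression value was in the files. A further 4 columns of per-peak values, 1 per list, repeated the score in 100% of rows and were not used. In 2 lists, 1 and 3 emptied lines were skipped.

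From these lists the number of peaks, genes with a peak, peaks per gene and peak width were counted, and groups were compared by an exact 2-sided permutation test of the means, for which 2 lists against 2 cannot give a p below 0.3333. Whether the replicates came from separate cultures is not given in the sources used here, so p-values measure only the spread between these samples, which may be technical. Peaks were called shared when they overlapped by at least 1 base. Regions were the union of all 4 lists with overlapping peaks joined. A gene or region was called control-only or knockdown-only when it had a peak in both lists of that group and in neither list of the other, and the counts were set beside those of the 2 other ways to split the 4 lists into pairs. Fold enrichment, score and false discovery rate are the authors' values and were used only to describe, rank or filter peaks within a list. The design text asks for the distribution of the modification; without a transcript annotation of the files' build this was done by chromosome, with Fisher's exact test of control-only against knockdown-only regions.

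Before the data were examined, 26 gene lists were fixed and tested by Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over the lists at 0.05: control-only against knockdown-only genes, and genes with a peak in all 4 lists against all genes with a peak. Genes are not replicates, so these p-values describe these 4 lists. Gene Ontology terms and KEGG pathways that the files give per gene, with at least 15 genes, were tested the same way after the data had been seen, against all genes with a peak and an annotation of that kind. Gene symbols are those of the files; 14282 of 14918 matched the RefSeq gene table of GRCh38 through their gene identifier, which was used for names only. The genes named were fixed by rule: NSUN2 and the other m5C machinery; mRNAs recalled as NSUN2 targets; the 10 genes with the highest mean within-list percentile of their strongest peak's fold enrichment among control-only genes, among knockdown-only genes and among genes in all 4 lists; and the 4 such members of each gene list past the threshold, of which some are not reported here. Genes outside this rule are said to be so where they appear. Silent families, fixed before their share was computed, were olfactory and bitter taste receptors, keratin-associated proteins, beta-defensins, late cornified envelope proteins and alpha interferons.

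Alternatives were a fold enrichment of at least 4, a p of at most 1e-10, lists cut to equal length by fold enrichment, a reciprocal overlap of 50%, peaks within 100 bases counted as shared, a peak in either replicate, same-numbered pairs, and leaving out each list. One alternative, added after seeing the data, left out peaks whose fold enrichment was a whole multiple of a step of the list, within 0.005; the step was the one between 0.25 and 0.6 with the most multiples. On simulated data with the 14918 genes, all 200 planted control-only genes were recovered beside 283 control-only genes that were not planted. Planted genes met the calling rule by construction, so their recovery gives no sensitivity for the real lists. A term drawn in part from the planted genes was called, which its make-up favoured, and 1 of 500 random terms was called. Planted multiples of a step were found in 100% of cases, and 2.77% of other values were taken for multiples. Planned tests of sequence composition, read counts and parts of the transcript were not run because the files hold none of these. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.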

Results

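Peaks of m5C enrichment were compared between control HCT15 cells and HCT15 cells with a short hairpin RNA against NSUN2, to describe the level and distribution of the modification in mRNA. The data comprise 2 control and 2 knockdown peak lists, each from an IP over its own input. The control lists held 20112 and 22282 peaks and the knockdown lists 23870 and 20361, counted as rows. Some rows shared chromosome, score, fold enrichment and false discovery rate with another row of their list, 1034 and 997 in control and 3199 and 2853 after knockdown. Whether such rows are parts of 1 called peak was not tested. Together the 4 lists named 14918 genes, of which 4494 (30.1%) had a peak in all 4 lists. The number of reads behind a peak is unknown, and no peak in any list had a false discovery rate of 5% or less in the authors' column, whose lowest values were 50% and 62.0% in the control lists and 29.6% and 25.1% in the knockdown lists.

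Transcripts of the m5C machinery were among the enriched RNAs, but no more often than other genes. Of the 14 members with a peak, 4 (28.6%) had one in all 4 lists, against 30.1% of all genes with a peak. NSUN2, the target of the hairpin, had 1 peak in control replicate 1 (chromosome 5, 6632997 to 6633418, fold enrichment 7.66) and 1 in knockdown replicate 1 (fold enrichment 5.41), and no peak in the other 2 lists; a peak is not an expression level, so this does not measure the knockdown. YBX1, which encodes a reader of m5C, had 5 peaks in every list, with the strongest at fold enrichments of 30.53 and 26.86 in the control lists and 21.31 and 19.01 in the knockdown lists; these were different peaks, at chromosome 1, 43166452 to 43166717, in both control lists, and from 43148658 and from 43148066 in the knockdown lists. YBX3 and the dioxygenase genes TET2 and TET3 also had peaks in all 4 lists. NSUN4, a mitochondrial methyltransferase gene, was the only member of the machinery list with a peak in both control lists (8.80 and 8.17) and in neither knockdown list, and no member showed the reverse. The strongest NSUN4 peaks of the control lists were different ones, on chromosome 1 from 46818540 and from 46812593. ALKBH1 and ALYREF had a peak in 1 list each, NSUN5 and NSUN7 in 2, and FMR1, NOP2, NSUN6 and TET1 in 3, while NSUN3, SRSF2, TRDMT1 and YTHDF2 had none, so 14 of 18 members had a peak in any list.

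Of 17 mRNAs recalled as NSUN2 targets, 11 had a peak. HDGF, which encodes a growth factor, had its strongest peak at chromosome 1, 156721135 to 156721543, in both control lists and knockdown replicate 1, with fold enrichments of 34.74 and 37.19 in the control lists and 26.82 and 26.63 in the knockdown lists. ICAM1 and TEAD1 also had peaks in all 4 lists. PKM, the pyruvate kinase of glycolysis, had weak peaks in both control lists (2.88 and 3.43), with the strongest at different positions, and none in the knockdown lists. QSOX1, GRB2 and SHC1 had peaks in both control lists and 1 knockdown list, FABP5 and CDKN2A in 1 list of each group, and CDKN1A and CDKN1B in control replicate 2. CDK1, ENO1, LIN28B, SKIL, SLC7A11 and TRIM28 had no peak. The list held 1 control-only and no knockdown-only member, too few for Fisher's exact test to have passed (unadjusted p = 0.2427).

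More genes carried a peak after knockdown, while the peaks were narrower and covered less sequence. A peak was found in 10212 ± 169 genes in the knockdown lists and in 8286 ± 416 in the control lists (mean ± SD, n = 2 each), 23.2% more, with both knockdown lists above both control lists. The median width was 169 ± 2.83 bases against 197.5 ± 3.54 bases, and peaks per gene were 2.16 ± 0.207 against 2.56 ± 0.0569. Peaks covered 5949009 ± 864569 bases in the knockdown lists and 8214706 ± 788995 in the control lists. Each of these 4 differences had an exact permutation p of 0.3333, the smallest that 2 lists against 2 can give, 2-sided. Widths are those of the deposited intervals. Some had the same start and end in all 4 separately called lists, as the strongest of ZC3H13 and HNRNPUL2 did. Others were very short, as the strongest of FBLN1 in knockdown replicate 2 (chromosome 22, 45961846 to 45961853). Whether intervals were cut at fixed bounds was not tested, so width, covered bases, peaks per gene and overlap may not be those of the called peaks. The number of peaks itself differed by less than the replicates did, at 22116 ± 2481 against 21197 ± 1534 (exact permutation p = 0.6667), and its direction turned at a p of at most 1e-10, where the difference of knockdown minus control was -656 peaks, and without control replicate 1 (-166.5) or knockdown replicate 1 (-836).

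**Figure D1:**
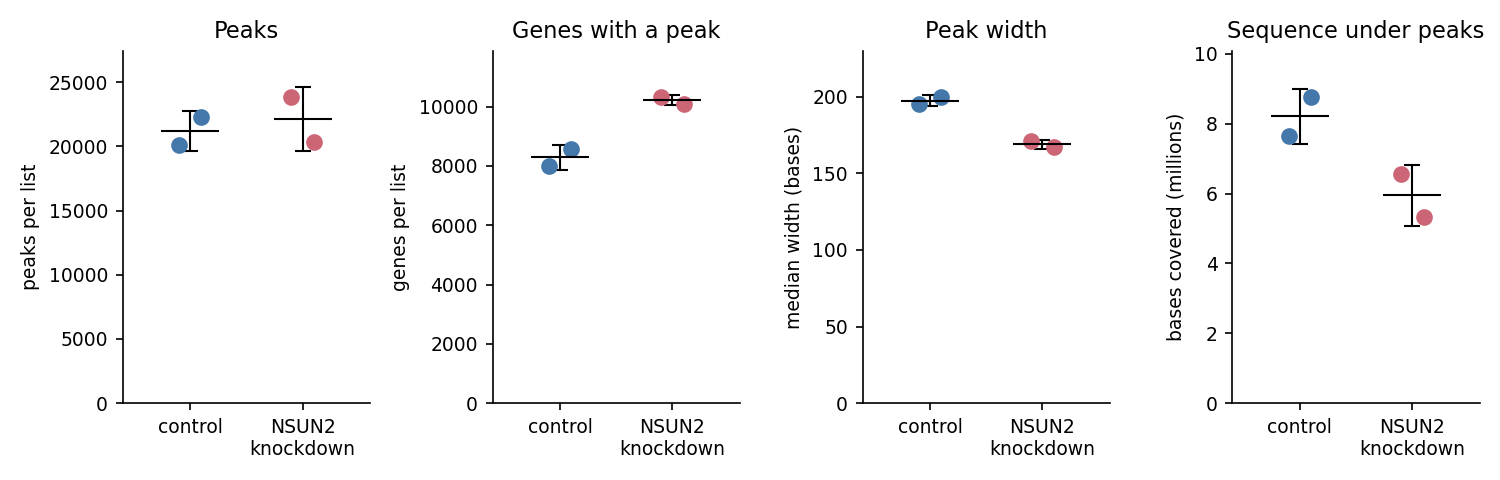
Peaks, genes with a peak, median peak width in bases and length covered by peaks for the control and the knockdown lists. Points are the 2 lists of each group and black bars their mean and SD; the knockdown lists lie above the control lists for genes (10331 and 10092 against 7992 and 8580) and below them for width (171 and 167 against 195 and 200 bases).

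Genes with a peak in only one group were mostly knockdown-only. Both knockdown lists and neither control list held a peak in 1317 genes, led by IRX3, a homeobox transcription factor gene, with fold enrichments of 213.3 and 216.5 (chromosome 16, 54320125 to 54320378, in knockdown replicate 1). LCLAT1, an acyltransferase gene, followed with 55.17 and 63.00, and TTF1, a gene of RNA polymerase I termination, with 46.30 and 66.42. LPA, ZNF718, PLA2R1, SF3A2, SLC8A3, SALL2 and ABCA9 completed the 10 highest ranked, with fold enrichments from 22.41 to 40.95. For 7 of these 10 genes, the leading IRX3 and also LPA and PLA2R1 among them, the strongest fold enrichment was a whole multiple of a step of the list, within 0.005, in both knockdown lists. It was so in 1 list for TTF1 and in neither for LCLAT1 and SF3A2. Both control lists and neither knockdown list held a peak in 422 genes, led by UFSP1, a gene of the ubiquitin-fold modifier pathway (90.93 and 95.96, chromosome 7, 100486344 to 100487339 in control replicate 1). HYPK, which encodes a huntingtin-interacting protein (59.50 and 61.22, at different positions), and C11orf68 (48.78 and 57.70) followed. HAGHL, ELFN2, NINJ1, COLCA2, GLTPD1, AK127224 and FTCD were the other 7, with fold enrichments from 14.24 to 54.15, those of FTCD at different positions. Whole multiples in both control lists were found for 5 of the 10, and not for UFSP1, HYPK or C11orf68.

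The 2 other splits of the 4 lists into pairs gave 808 and 904 such genes in both directions together, against 1739 for control against knockdown; with 3 splits no share under 0.05 can be reached. The excess of knockdown-only genes, 3.12 times the control-only number, was not kept when the peaks of a gene in both replicates had to overlap reciprocally by 50% (273 knockdown-only and 284 control-only genes, a ratio of 0.961), and fell to 1.33 times where they had to lie within 100 bases. The 2 knockdown replicates had overlapping peaks in 30.4% of the knockdown-only genes, and the 2 control replicates in 74.4% of the control-only genes.

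**Figure D2:**
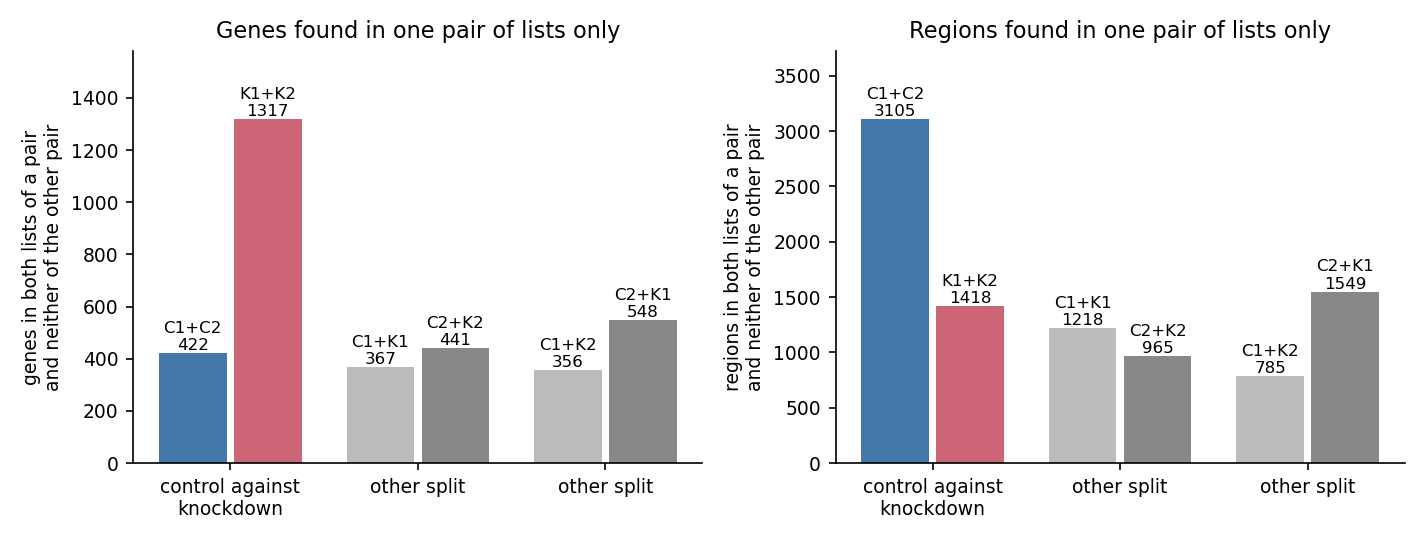
Number of genes (left) and merged peak regions (right) with a peak in both lists of a pair and in neither list of the other pair, for control against knockdown and for the 2 other splits; C1 and C2 are the control and K1 and K2 the knockdown lists. For genes the knockdown bar (1317) is the tallest of all, and for regions the control bar (3105) is.

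By position, the direction was the opposite with both replicates required. The 4 lists merged into 49457 regions, 5464 (11.05%) of them with a peak in every list. Control-only regions numbered 3105 and knockdown-only regions 1418, against 2183 and 2334 in both directions together for the other 2 splits. The genes with the most control-only regions, named after their values were seen, were LRP1, a lipoprotein receptor gene, with 11, and HUWE1, a ubiquitin ligase gene, with 10. Neither had a knockdown-only region, but both kept other peaks after knockdown. LRP1 had 13 and 8 peaks in the knockdown lists against 20 and 24 in the control lists, and HUWE1 had 5 and 5 against 19 and 17. Transcript length was not accounted for. ARHGEF10L, HSPG2 and VAV2 had 8 control-only regions each and no knockdown-only region, and RAPGEF1 had 8 and 2. With a peak in either replicate enough, knockdown-only regions outnumbered control-only ones, 20086 to 13908, and they did so without knockdown replicate 1 (a ratio of 1.73) or 2 (2.52), where 1 knockdown list needs no replicate.

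The control replicates shared more of their peaks than the knockdown replicates. Of the peaks in the control lists, 64.2% and 57.8% overlapped a peak of the other control list, with a Jaccard index of 0.523 by bases. In the knockdown lists 34.2% and 40.04% did, with a Jaccard index of 0.295. The 4 pairs of 1 control and 1 knockdown list had indices of 0.280 to 0.372, so by position the knockdown pair lay within the range of the pairs between groups, above only that of control replicate 2 and knockdown replicate 2. Across genes the indices were 0.591 between control lists, 0.538 between knockdown lists and 0.486 to 0.529 between groups. Over the 3 splits, within-pair minus between-pair indices by bases were 0.0834 for the real groups and -0.0416 and -0.0418 for the others. Peaks shared with the replicate were the stronger ones in each list, with a median fold enrichment of 9.88 against 6.33 and 11.11 against 6.6 in the control lists, and 12.99 against 8.62 and 10 against 8 in the knockdown lists. The median fold enrichment over all peaks was 8.09 and 8.33 in the control lists and 9.81 and 8.62 in the knockdown lists.

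Chromatin regulators, Wnt components and colon epithelial genes were the groups most often enriched in every list. Transcript length and expression were not accounted for, so the odds ratios do not separate m5C from either. The background of 14918 genes included 4401 with a peak in 1 list only. Of 38 chromatin modifier genes with a peak, 33 had one in all 4 lists (odds ratio 15.4, Fisher's exact test, adjusted p = 1.38e-11), among them ARID1A and SMARCA4 of the SWI/SNF remodelling complex, and KDM6B. Wnt signalling had 20 of 32 (odds ratio 3.88, adjusted p = 0.00139, exact test), with TNKS, BCL9L, NKD1 and LRP5, and colon epithelium 13 of 19 (odds ratio 5.04, adjusted p = 0.00416, exact test), with MUC2, the main secreted mucin of goblet cells, CLDN3 and MUC1. MUC2 had fold enrichments of 132.6 and 111.8 in the control lists and 100.2 and 54.02 in the knockdown lists. Splicing factors had 20 of 40 (odds ratio 2.33, adjusted p = 0.0464, exact test), with SRSF4, RBM25, HNRNPM and HNRNPUL2. Genes named ZNF, mostly zinc finger transcription factors, were enriched in all lists less often, 81 of 400 (odds ratio 0.581, adjusted p = 9.28e-05, exact test), with ZNF703, ZNF205, ZNF827 and ZNF83 the highest ranked. Wnt signalling did not pass at a p of at most 1e-10 (exact test, adjusted p = 0.0864), and splicing factors did not pass without control replicate 1 (exact test, adjusted p = 0.265) or without knockdown replicate 1 (exact test, adjusted p = 0.101).

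The strongest genes in all 4 lists were INCENP, a gene of the chromosomal passenger complex with fold enrichments from 311.3 to 827.4, CDK11B, a kinase gene, ZC3H13, a gene of the m6A methyltransferase complex (304.0 to 856.6), and RRBP1, a ribosome-binding protein gene (351.3 to 959.5). PLEKHA4, SLTM, EIF5B, GNB1, MAP7D1 and HDGFRP2 followed. The peak of ZC3H13 at chromosome 13, 46549418 to 46549973, and that of RRBP1 at chromosome 20, 17662673 to 17662940, were the strongest of their gene in all 4 lists.

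Other gene lists did not pass for a peak in all 4 lists, where 30.1% of all genes with a peak had one. The counts in all 4 lists were 8 of 15 aminoacyl-tRNA synthetases, 8 of 16 genes of the unfolded protein and integrated stress response, 9 of 18 heat shock proteins and chaperones and 8 of 16 m6A machinery genes. They were 17 of 37 for MAPK and PI3K signalling, 15 of 37 for cell cycle, 15 of 39 for translation initiation and elongation factors, 6 of 16 for the p53 pathway and 5 of 14 for glycolysis. Mitochondrial ribosomal proteins had 10 of 32, DNA repair 8 of 26, ferroptosis 4 of 14, m5C machinery 4 of 14, recalled NSUN2 targets 3 of 11 and the interferon response 4 of 16. Autophagy had 5 of 21, oxidative phosphorylation 9 of 38, blood and immune markers 2 of 10, replication-dependent histones 2 of 11, fibroblast and mesenchymal markers 4 of 21 and cytosolic ribosomal proteins 3 of 20.

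**Figure D3:**
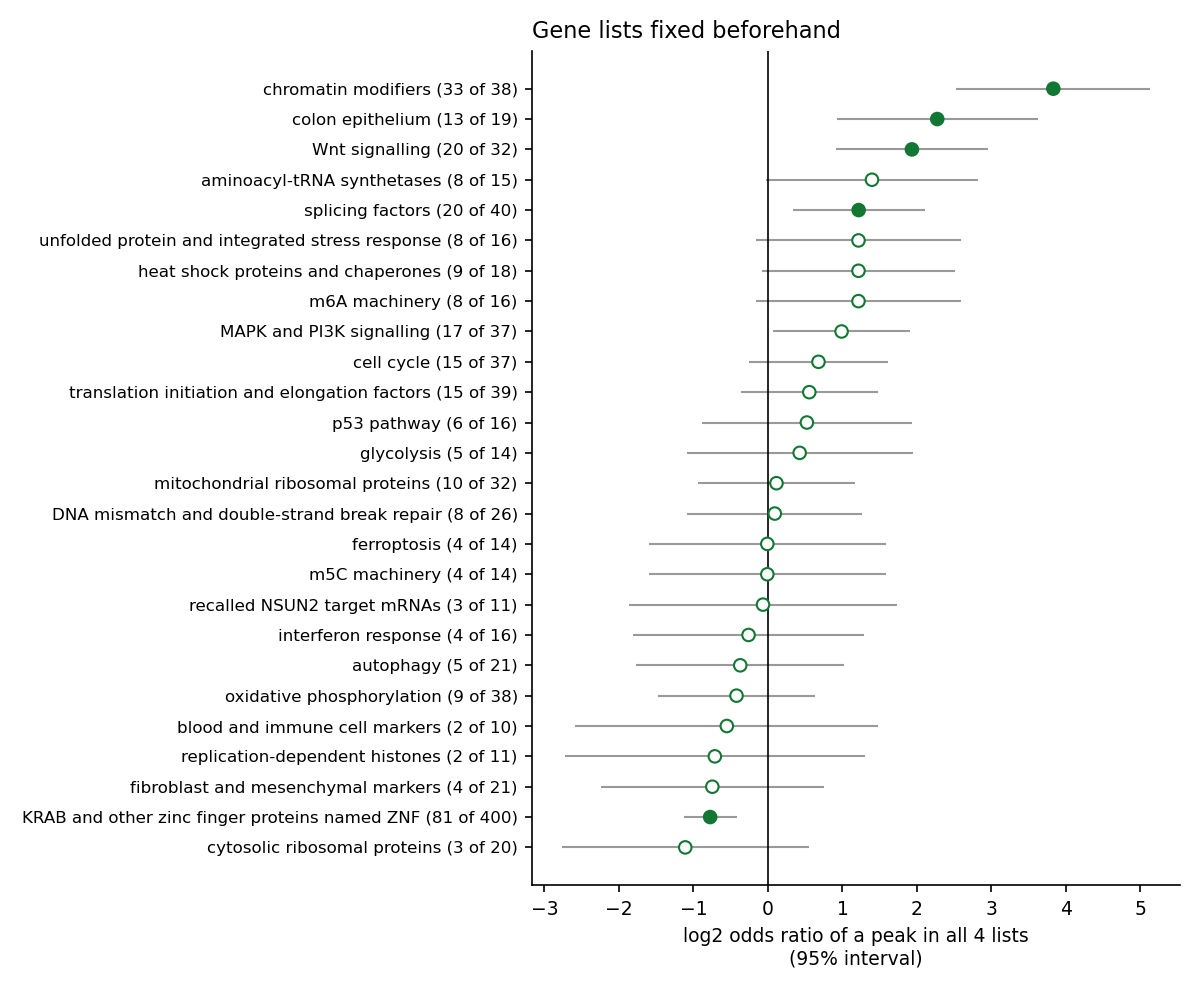
Log2 odds ratio of having a peak in all 4 lists for members of each of 26 gene lists against other genes with a peak, with 95% intervals (a small constant added to each cell of the table). Filled points passed Fisher's exact test after Benjamini-Hochberg adjustment, 4 of them above and the ZNF genes below 0.

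Between the groups no gene list separated control-only from knockdown-only genes. Of 26 lists, none passed Fisher's exact test after adjustment (smallest adjusted p = 0.36) and 1 did before it. That list was translation initiation and elongation factors, with 4 control-only and 1 knockdown-only members (exact unadjusted p = 0.0139). Fibroblast and mesenchymal markers had 5 knockdown-only and no control-only members, and ZNF genes 40 and 9, against 1317 and 422 for all genes. Without knockdown replicate 1, Wnt signalling passed, with 6 control-only and no knockdown-only members (exact test, adjusted p = 0.0140).

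Among the terms the files give per gene, which were tested after the data were seen, knockdown-only genes held more secreted and membrane proteins. The extracellular region took 143 of 1149 annotated knockdown-only genes, 12.4% against 6.999% of the rest (odds ratio 1.89, Fisher's exact test, adjusted p = 4.88e-08). The extracellular matrix term took 35 (odds ratio 3.15), collagen trimer 13 (odds ratio 3.004) and cholinergic synaptic transmission 10 of its 25 genes (odds ratio 6.99, adjusted p = 0.0210, exact test). Highest ranked were LPA and PLA2R1, which encode an apolipoprotein and a phospholipase receptor, in the extracellular region, FBLN1 and DEFA1 in the matrix term, C1QTNF9 and COL14A1 in collagen trimer, and the acetylcholine receptor subunit genes CHRNA9 and CHRNA2 in the cholinergic term. Between the 2 knockdown lists the strongest peaks of CHRNA9 and CHRNA2 overlapped. Those of LPA, PLA2R1, FBLN1, DEFA1, C1QTNF9 and COL14A1 lay at different positions. Nucleoplasm (odds ratio 0.432) and poly(A) RNA binding (odds ratio 0.343, 26 genes) were under-represented. No term passed for control-only genes, with 31 of 899 biological process, 9 of 300 cellular component, 14 of 399 molecular function and 7 of 239 pathway terms under 0.05 by Fisher's exact test before adjustment.

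The knockdown lists also held more genes of families assumed beforehand to be silent, 76 and 93 (0.736% and 0.922% of genes with a peak), than the control lists, with 20 and 25 (0.2503% and 0.291%). Expression of these families in this line was not measured. Fold enrichments often fell on whole multiples of a step, 0.352 and 0.347 in the control lists and 0.427 and 0.4001 in the knockdown lists. Among peaks of knockdown-only genes 76.2% and 79.03% did so, against 29.2% and 30.9% in genes with a peak in all 4 lists; among peaks of control-only genes the shares were 36.4% and 37.3%, against 26.6% and 26.2%. Chance gives 2.39% to 2.94%. With those peaks left out of all lists, a setting added after seeing the data, 371 genes were knockdown-only and 427 control-only. These are partly other genes: 255 of the 371 were among the 1317 and 250 of the 427 among the 422. The odds ratio of the extracellular region was 0.866 among the 371 (exact test, unadjusted p = 0.778) and 0.954 among the 255 (9 of 221 annotated genes).

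**Figure D4:**
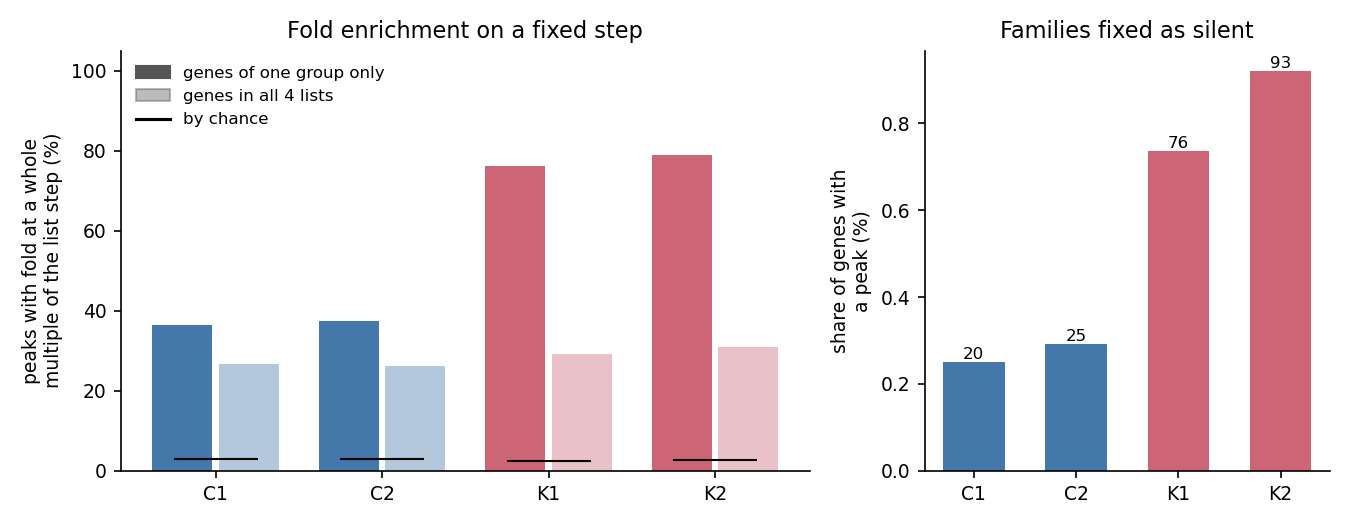
Left, share of peaks whose fold enrichment is a whole multiple of the list's step, in percent, for genes found in one group only and for genes in all 4 lists, with the share chance gives as black lines; right, share of genes with a peak that belong to families fixed as silent, in percent, with their number above each bar. C1 and C2 are the control and K1 and K2 the knockdown lists; the knockdown-only bars reach 76.2% and 79.03%.

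By chromosome, both knockdown lists lay on the same side of both control lists in share of peaks for 19 of 24 chromosomes, 11 higher and 8 lower after knockdown; chance gives 33.33% per chromosome, and the shares are not independent. Chromosome 22 fell from 3.59 ± 0.170% to 2.79 ± 0.0805% and chromosome 6 rose from 4.02 ± 0.0357% to 4.47 ± 0.0644% (n = 2 each). Chromosome 19 held 9.12 ± 0.263% of the peaks in the knockdown lists and 9.996 ± 0.0803% in the control lists (n = 2 each), and chromosome 1 held 10.2% and 10.1%. Over regions, chromosome 22 had the smallest p, with 4.99% of control-only and 3.10% of knockdown-only regions (Fisher's exact test, adjusted p = 0.0901), and no chromosome passed after adjustment.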

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

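The test of NSUN2 loss and the draws from list sizes were chosen after their result, or one close to it, had been seen, and the fold enrichment steps were noticed in the data; the other tests were set out before their results. The names of the peaks carry a running number that the comparisons did not use, and its highest value was 374344 and 480896 in the knockdown lists, above the 200245 and 217787 of the control lists. The lists hold 6.38% and 4.23% of the numbered peaks after knockdown and 10.04% and 10.2% in the control.

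More genes had a peak after knockdown, 1317 knockdown-only against 422 control-only. A larger number of peaks alone did not account for it, since the ratio was 2.66 at equal list length and 2.14 at a p of at most 1e-10. Draws from each gene's share of lists and the number of genes per list gave a ratio of 2.565 (748 ± 25.3 and 291 ± 17.3 genes, mean ± SD of draws). These draws take the larger gene number of the knockdown lists as given, so they cannot explain it. Both observed counts were above the drawn ones. The excess was absent without peaks on the fold enrichment steps (0.869) and at a reciprocal overlap of 50% (0.961), so its cause remains open. Leaving out peaks on the steps took 76.2% and 79.03% of the peaks of knockdown-only genes, and 36.4% and 37.3% of those of control-only genes. A fall in the ratio was therefore built into that setting, which is no independent check. The overlap setting is none either. It dropped genes whose replicate peaks did not overlap, and replicate peaks overlapped in 30.4% of knockdown-only and 74.4% of control-only genes. The share of genes in silent families such as olfactory receptors was 3.06 times higher in the knockdown lists, which is consistent with more background from DNA or from sparse transcripts, and that remains open as an explanation for part of the pattern. A loss of NSUN2-dependent m5C could lower the number of genes with a peak. It need not, since a gene is counted while any of its peaks remains. Here the ratio of knockdown-only to control-only was 3.12 for genes but 0.457 for regions, and 0.869 and 0.3045 without peaks on the steps. The counts therefore do not decide on it.

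Knockdown-only genes were richer in secreted and membrane proteins. For the extracellular region, the only such term put to these tests, this was not a property of every gene found in few lists, because among genes in exactly 2 lists the odds ratio was 1.963 for the knockdown pair over the mixed pairs (12.4% against 6.75%, Fisher's exact test, p = 8.20e-07). It was not limited to peaks near the threshold either, with an odds ratio of 1.901 at a p of at most 1e-10. Without peaks on the fold enrichment steps the odds ratio was 0.866, and 0.954 among the genes that were knockdown-only with all peaks as well. That setting took 76.2% and 79.03% of the peaks of knockdown-only genes, and the second value rests on 9 of 221 annotated genes. It is therefore no independent check of the term. A candidate explanation is that the caller's background stood at a fixed minimum for peaks on the steps because the input held few reads. That could hold for genes scarcely expressed in this line. No input level was given to test it directly.

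Genes and regions went in opposite directions with all peaks and both replicates required, but not without peaks on the steps (ratios of 0.869 and 0.3045) or at a reciprocal overlap of 50% (0.961 and 0.3408). Neither setting is an independent check. The first took a larger share of the peaks of knockdown-only than of control-only genes. The second dropped genes whose replicate peaks did not overlap, which were more frequent among knockdown-only genes. Overlapping peaks in both replicates were 0.408 times as frequent in knockdown-only genes (30.4%) as in control-only genes (74.4%), and with a peak in either replicate enough the ratio of knockdown-only to control-only was 1.44 for regions and 2.74 for genes. Both values are consistent with the region count following how well replicates placed their peaks, which may be technical. A biological change in where m5C lies after NSUN2 loss was not tested apart from this.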

How the results depend on the processing

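The settings without peaks on the fold enrichment steps, and all of those for the extracellular region, were chosen after seeing the data. Over 24 results and 172 comparisons with an alternative, 127 counted as the same: for differences the direction, for odds ratios also the side of the threshold, for counts and their ratios within 1.5 times, and for fold enrichment within 1 SD of the lists of a group. Sizes could still change, as for the odds ratio of chromatin modifiers, 15.4, which ran from 8.13 to 26.5. The genes with a peak, their peaks per gene, the median width and the share of peaks on chromosome 19 kept their direction in every setting reported for them. Chromatin modifiers, colon epithelium and ZNF genes kept their direction and their side of the threshold. None of these results was examined without peaks on the fold enrichment steps, a setting that turned the excess of knockdown-only genes. Lists of equal length were not reported for genes with a peak, peaks per gene or median width. For the results below the cause was not tested, except that fewer lists or a looser rule admit more genes by construction. At a p of at most 1e-10, the difference in number of peaks was -656, knockdown-only regions numbered 722 and the ratio of knockdown-only to control-only regions was 0.271. With a reciprocal overlap of 50%, knockdown-only genes numbered 273 and the ratio for genes was 0.961; within 100 bases they numbered 422, a ratio of 1.33. With a peak in either replicate, control-only and knockdown-only genes numbered 1641 and 4499, and regions 13908 and 20086, a ratio of 1.44. Without peaks on the steps, knockdown-only genes numbered 371, the ratio for genes was 0.869, knockdown-only regions 712, and the odds ratio of the extracellular region 0.866, or 0.954 among genes also knockdown-only with all peaks. From the mean of log2 values in place of the median, fold enrichment was 9.34 and 9.58 in the control lists and 10.72 and 9.32 in the knockdown lists. Leaving out each list in turn gave ranges. Control-only genes ran from 876 to 1205, knockdown-only genes from 1934 to 3012, and their ratio from 1.69 to 3.201. Control-only regions ran from 4425 to 9436, knockdown-only regions from 2022 to 11167, and their ratio from 0.219 to 2.52. The ratio for regions was above 1 without knockdown replicate 1 (1.73) or 2 (2.52). The difference in number of peaks ran from -836 to 2673, turning without control replicate 1 (-166.5) or knockdown replicate 1. The share of peaks shared within minus between groups, 5.47 percentage points, ran from -7.12 to 20.7; it was -5.82 without control replicate 1 and -7.12 without control replicate 2, which leave only the knockdown pair. Gene lists that separated control-only from knockdown-only genes numbered 0 to 1. Same-numbered lists share only a number: the correlation across genes of their deviations was -0.017. As a replicate block, they gave the same 422 and 1317 genes by construction, a mean within-pair difference of 918.5 peaks (exact sign-flip p = 1.0) and of 1926 genes with a peak (exact p = 0.5, the smallest 2 pairs can give). Not run, for want of sequence, counts or transcript parts, were the alternatives for sequence composition, read counts and the peak middle. Counting each interval once changed nothing, since all rows were separate intervals. That does not show that each row is a separate called peak. Rows that shared all peak values with another row numbered 1034 and 997 in the control lists and 3199 and 2853 in the knockdown lists, and counting those once was not tried. Depth is unknown, so what it limits cannot be given.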

Other observations

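These tests were all chosen after the data were seen. Genes with a peak in all 4 lists were rich in RNA-binding and cytoskeletal proteins, with transcript length and expression again not accounted for. Poly(A) RNA binding took 449 of 3988 annotated genes (11.3% against 4.07% of the rest, odds ratio 2.99, Fisher's exact test, adjusted p = 1.29e-46), nuclear speck 83 of its 149 genes (odds ratio 2.77, adjusted p = 2.69e-08, exact test), stress fiber 35 of 49 (odds ratio 5.48, adjusted p = 3.81e-07, exact test) and focal adhesion 160 of 306 (odds ratio 2.44, adjusted p = 1.24e-12, exact test). None of the 125 olfactory receptor genes with a peak had one in all 4 lists.

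Genes with a control-only region and no knockdown-only region numbered 1878, and the reverse 1059. The first group held more poly(A) RNA-binding genes, 9.54% against 4.47% (odds ratio 2.25, Fisher's exact test, adjusted p = 0.00116), and the second more genes of calcium signalling, 20 of its annotated members against 11 (odds ratio 0.258 for control over knockdown, adjusted p = 0.0183, exact test), and of olfactory transduction, 11 against 2 (adjusted p = 0.0135, exact test). No gene list fixed beforehand separated them by Fisher's exact test after adjustment, and 1 of 26 did before it, Wnt signalling with 10 genes against none (exact unadjusted p = 0.0172). MYRF and NOD1, named after their values were seen, had 3 knockdown-only regions each and no control-only region. MYRF had 9 and 6 peaks in the knockdown lists against 3 and 2 in the control lists, and NOD1 had 4 and 6 against 0 and 1.

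The false discovery rate in the authors' column was higher for peaks with high scores. For scores of at least 1000 its medians were 100% and 81.6% in the control lists and 100% in both knockdown lists, and for scores under 200 they were 86.1% and 72.0%, and 31.0% and 26.3%. Over all peaks the medians were 100% and 82.8% in the control lists and 33.9% and 29.1% in the knockdown lists. It stood at 100% for 51.5% and 13.7% of control peaks and 12.6% and 11.2% of knockdown peaks.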
